A study of Mus musculus with 20 samples.

How the data were processed

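Total RNA of 20 ventricle samples, 5 in each of 4 groups, was measured on Affymetrix mouse arrays after biotin labelling of 100 ng RNA, per the labels. The deposited values are on a log2 scale, 1 value for each of 45101 probe sets and each array. The log2 unit was read from the values, which run from 5.07 to 15.31, because the log base, the summarization software and the between-array normalization used by the authors are not given in the sources used here. Array means were nearly equal, and array medians and spreads were not identical. A change of 1 is taken as 2-fold throughout, which rests on that reading. No background signal per probe was used, so a level near the bottom of the range is not separated from background.

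From these values, 64 control probe sets were left out. Of the rest, 34945 probe sets were paired with exactly 1 gene symbol in the platform annotation, 932 with several symbols and 9160 with none, and genes were named only from the first kind. Counting the 13 controls that also carry 1 symbol, gene IDs of 34754 of 34958 probe sets were found in the reference gene table (GRCm38.p6), through which no symbol had to be changed. Coordinates were not used here. Probe sets with a mean over all arrays above the median of all probe sets (6.93) were kept, and each gene was represented by the probe set with the highest mean over all arrays, which left 12082 of 18193 genes.

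Samples were grouped by their titles. Samples titled beta carry a treatment label of control solution, and were kept as a group of their own. All 20 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit with group means, eBayes with an intensity trend), and contrasts were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Gene lists, 31 in all, covered energy metabolism, contraction, hormone response, stress and markers of cell types a ventricle sample could hold, and were fixed before the data were examined. The 30 lists with at least 3 tested members were tested with camera at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Some list symbols were not matched to a probe set with 1 symbol, and the mesothelium list, with 2 tested members, was not tested.

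The genes named were chosen by a rule set before the data were examined. For each comparison with placebo these were up to 12 of the largest rises and 12 of the largest falls among called genes, or the 10 genes of smallest p where fewer than 10 passed. For each comparison between treated groups they were up to 5 rises and 5 falls, or the 5 of smallest p. Up to 4 called members of each list were added, and Slc2a1, Slc2a4, Esr1, Esr2, Nppa, Myh7 and Pdk4 were always named. Other members of lists named as examples, the genes named for passing over their list alone, and the comparison of Slc2a1 and Ptgds between groups other than placebo were chosen after their values were seen.

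Alternatives covered the filter, the summary of probe sets, the scaling of arrays, array weights, the groups entering the fit, the replicate number as a block, pooled controls, the threshold, and leaving out each array in turn. Leaving out the 3 arrays with the narrowest spread, and correlations without shared arrays, were added after the data were examined. The fit was tested on simulated data, drawn from the real means and spreads: with 200 of 12082 genes changed between 16α-LE2 and placebo, 50.2% of genes changed by 0.4 log2 units and 96.1% of those changed by 0.8 were recovered over 10 runs, and 4.82% of calls were false. Each gene was drawn independently there, so these shares need not hold for the real arrays, on which genes can deviate together. Figures were drawn with matplotlib 3.10.9.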

Results

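Gene expression was measured on 20 arrays, 1 for each sample of heart ventricle, from female C57BL/6 mice that were ovariectomized at 8 weeks of age and then treated through an implanted minipump for 4 weeks. Ovariectomy removes the main source of circulating estrogen, and the series asks how estrogen receptor α acts on the heart, with glucose uptake as its theme. The 4 groups of 5 samples each were compared: placebo, 17β-estradiol (an agonist of both classical estrogen receptors), 16α-LE2 (described in the labels as an agonist of receptor α), and a group whose titles say beta while their treatment label says control solution. Because these labels disagree, the last group is called the beta-titled group and was kept apart from placebo. Doses are not given in the labels, so the agonists were compared at the same duration but not at a known common dose. Of 18193 genes on the array with an unambiguous probe set, 12082 lay above the expression filter and were tested, and the median half-width of the 95% confidence interval of a difference between 2 groups was 0.21 log2 units. The number of arrays limits this precision. The p-values measure the spread between the samples of a group, estimated over all 4 groups together. An array outside a comparison therefore also affects its p-values. The labels do not tie the samples to animals in so many words. Spearman correlations between arrays were 0.978 to 0.992 except for those of estradiol replicate 33, which were 0.922 to 0.941. The SD of the values on an array, averaged by group, was 1.44 log2 units for placebo, 1.41 for estradiol, 1.39 for 16α-LE2 and 1.38 for the beta-titled group.

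The first comparison asked what stimulation of receptor α did to the ventricle, as 16α-LE2 against placebo. Several collagen and other matrix genes were among those that fell, while Spon1, another matrix gene, rose. Sparc, a secreted collagen-binding glycoprotein, fell by 0.99 ± 0.11 on the log2 scale (SE; limma adjusted p = 0.000102), from 11.84 ± 0.14 to 10.85 ± 0.18 (SD, n = 5 in each group). Col3a1, a fibrillar collagen, was 2.79-fold lower (limma adjusted p = 0.0011), and Nrep, a neuronal regeneration-related protein, was 2.37-fold lower (limma adjusted p = 0.00209). Aplnr, the apelin receptor, fell by 1.58 ± 0.30 on the log2 scale (SE; limma adjusted p = 0.0219), although its values overlapped between the groups. In the other direction Myh7, which encodes the β myosin heavy chain of the sarcomere, was 2.55-fold higher (log2 change 1.35 ± 0.22 SE, limma adjusted p = 0.00733), with all 5 treated samples above all 5 placebo samples.

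In all, 27 genes passed the threshold with 16α-LE2, 3 higher and 24 lower, while 1088 genes had an unadjusted p under 0.05. Here and below, a share of about 0.05 of the 12082 tested genes would reach such a p with no change at all. Only the counts for 16α-LE2 and for estradiol against placebo lay well above that share. The count for the beta-titled group against estradiol lay below it. The other genes that rose with 16α-LE2 were Slc4a1, the anion exchanger of red blood cells (1.49-fold, limma adjusted p = 0.0256), and Spon1, a secreted matrix protein (1.47-fold, limma adjusted p = 0.031). Besides those above, the largest falls were those of Marcks, a substrate of protein kinase C (1.80-fold lower), Fstl1 (1.71-fold), Itih5 (1.67-fold), Smoc2, a secreted calcium-binding matrix protein (1.66-fold), Ppic (1.64-fold), Col8a1 (1.63-fold), Col5a2 (1.57-fold) and Mmp2, a gelatinase (1.56-fold), with limma adjusted p from 0.00733 for Fstl1 to 0.0323 for Marcks and Col8a1. Most other probe sets of these genes moved in the same direction. However, 1 of the 3 for Sparc and 1 of the 7 for Marcks were close to 0 with the opposite sign. Another for Slc4a1 had a log2 change of 0.01, and another for Aplnr had one of −0.41. Others were smaller in size than the one used: −0.85 for Col3a1, −0.87 for Nrep, −0.27 for Col5a2, −0.29 for Col8a1 and 0.28 for Spon1. Those of Fstl1, Mmp2 and Smoc2 and a remaining one of Sparc lay nearer to the one used, at −0.64, −0.63, −0.66 and −1.02. With the mean of a gene's probe sets, Sparc had a log2 change of −0.654 and still passed, and those of Slc4a1, Aplnr and Marcks were 0.293, −0.997 and −0.480, and did not pass. The number of genes depended on single arrays: it was 74 without estradiol replicate 33, 8 and 15 without placebo replicates 31 and 33, and 11, 9 and 14 without 16α-LE2 replicates 30, 33 and 34. Estradiol replicate 33 is not in this comparison and acts on the count only through the shared estimate of the spread. After quantile normalization 23 genes passed, 7 higher and 16 lower, and with array weights, which gave estradiol replicate 33 a weight of 0.079, 357 genes passed. Of 31 alternative settings run for each named gene, Sparc, Col3a1, Nrep and Myh7 passed in all. The call was lost in 11 for Col8a1, 10 each for Marcks and Spon1, 8 for Slc4a1, 7 each for Ppic and Mmp2, 6 for Col5a2, 5 for Aplnr, 3 for Itih5 and 1 each for Fstl1 and Smoc2.

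**Figure D1:**
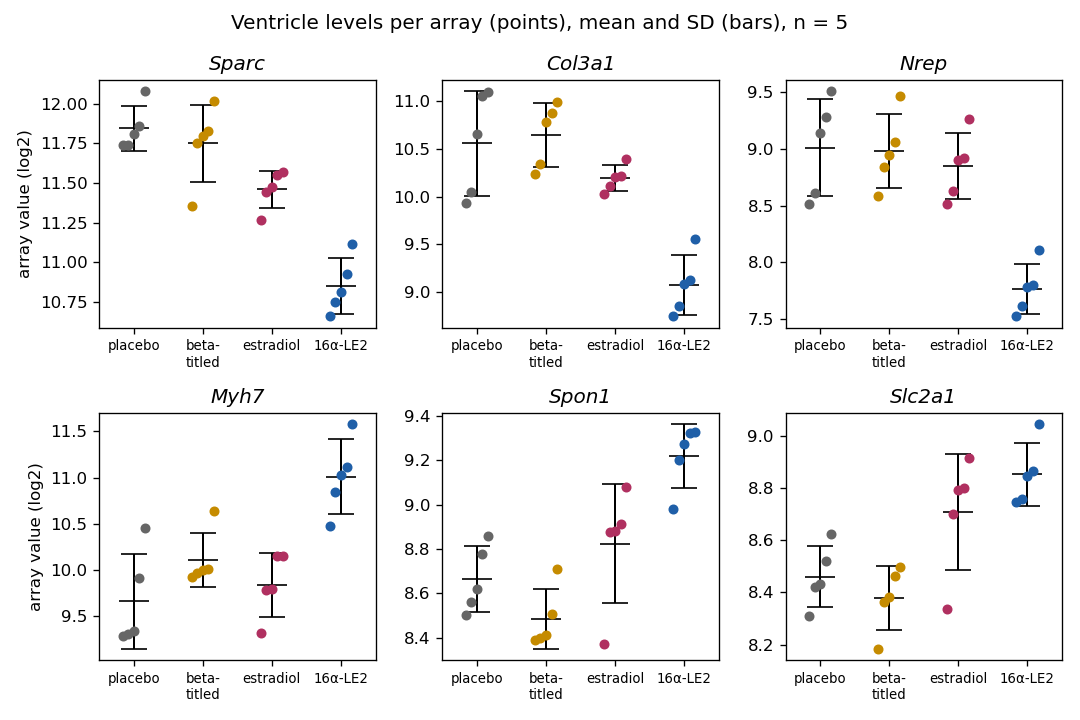
Array values on the log2 scale (vertical axes, which do not start at 0) for 6 genes in the 4 groups; points are arrays, and bars are the group mean and SD (n = 5). Sparc averaged 11.84 with placebo and 10.85 with 16α-LE2, and Myh7 averaged 9.66 and 11.01.

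Among the gene lists fixed before the data were examined, the extracellular matrix and fibroblast list fell with 16α-LE2. Of its 29 tested members, 25 had a negative change, 7 passed over all genes, and 13 passed adjusted over the list alone. The 7 were Sparc, Col3a1, Fstl1, Col5a2, Col14a1, Mmp2 and Col8a1, and members such as Timp1, an inhibitor of matrix proteases, did not pass (log2 change 0.01 ± 0.11 SE). The median change of the list was −0.30 (camera adjusted p = 1.21e-13), and the call held with an estimated correlation (adjusted p = 0.046). The red blood cell list rose, with a median change of 0.54 over 6 tested members (camera adjusted p = 8.97e-08; adjusted p = 0.046 with an estimated correlation). Slc4a1 passed over all genes, and adjusted over the list alone Slc25a37, Alas2 and Bpgm passed as well, while the α-globin gene Hba-a1, with a log2 change of 0.06 ± 0.09 SE, did not.

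The endothelium list had a median change of −0.26 (camera adjusted p = 0.00375), with no member past the threshold over all genes and 9 of 18 adjusted over the list alone. These went both ways, since Tek, Cldn5 and Aqp1 had log2 changes of −0.57, −0.88 and −0.55 while Vwf, the von Willebrand factor gene, had 0.66 and Flt1 had 0.31. With an estimated correlation the call was lost (adjusted p = 0.664), and it was also lost without placebo replicate 32 or without placebo replicate 34. The interferon response list had a median change of −0.44 (camera adjusted p = 3.74e-05), with all 14 members negative and none past the threshold over all genes or over the list alone. This call was lost with an estimated correlation (adjusted p = 0.664) and without placebo replicate 36, where the median was −0.19 (camera adjusted p = 0.114). Without placebo replicate 36 the number of lists was 7. The remaining 26 of 30 tested lists did not pass, among them the sarcomere list, in which Myh7 was the 1 member of 22 that changed.

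Genes of glucose handling were the stated theme. Slc2a1, which encodes the glucose transporter GLUT1, was 1.31-fold above placebo with 16α-LE2 (log2 change 0.39 ± 0.10 SE), with all 5 treated samples above all 5 placebo samples. It did not pass over all genes (limma adjusted p = 0.118), nor without the expression filter (limma adjusted p = 0.16). It passed adjusted over the list alone (adjusted p = 0.0151), and over all genes without estradiol replicate 33 (limma adjusted p = 0.0203). That array is not in this comparison: without it the log2 change stayed at 0.39 and the SE went from 0.10 to 0.08. Of the 3 probe sets for Slc2a1 on the array, only that of highest mean is given here. Irs2, an insulin receptor substrate, was 1.32-fold above placebo (limma adjusted p = 0.175; adjusted p = 0.0257 over the list alone). Slc2a4, which encodes the insulin-responsive transporter GLUT4, had a log2 change of −0.03 ± 0.10 SE (limma adjusted p = 0.973), and its sign turned after quantile normalization, when placebo and beta-titled samples were pooled, and without placebo replicate 34. Pdk4, a kinase that restrains pyruvate dehydrogenase, had a log2 change of −0.27 ± 0.20 SE (limma adjusted p = 0.751). Of the 24 tested members of the glucose uptake and insulin signalling list, 10 were above and 14 below placebo. The median of the list was −0.03, its mean was 0.02 and the test pointed up without passing (camera adjusted p = 0.19). Esr1 and Esr2, the estrogen receptor genes, lay below the expression filter with means of 6.89 and 6.54 and were not tested. Nppa, the atrial natriuretic peptide gene, was 1.33-fold above placebo and did not pass (limma adjusted p = 0.532).

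Estradiol against placebo asked what the natural agonist did. No gene passed with limma (smallest adjusted p = 0.275), although 1163 genes had an unadjusted p under 0.05. This was also 0 with array weights and after quantile normalization, and 1 gene passed without 16α-LE2 replicate 29. The 10 genes of smallest p, none of which passed, were led by Tmem100 (log2 change −0.73 ± 0.14 SE), Sfpq, an RNA-binding splicing factor (−0.67 ± 0.14), Klf4, a zinc finger transcription factor (−0.66 ± 0.14), and Tmcc3 (−0.59 ± 0.13), each with a limma adjusted p of 0.275. Meig1, Palmd, Slc38a2, Atp13a3 and Adamts9 were also below placebo, and Bace2, an aspartyl protease, was 1.28-fold above it. Slc2a1 was 1.19-fold above placebo (log2 change 0.25 ± 0.10 SE, limma adjusted p = 0.499), in 4 of 5 samples above the placebo mean. Without estradiol replicate 33 its log2 change was 0.34 ± 0.08 SE (limma adjusted p = 0.759). Slc2a4 (0.01 ± 0.10), Myh7 (0.18 ± 0.22), Nppa (0.10 ± 0.19) and Pdk4 (−0.59 ± 0.20) had log2 changes that did not pass either. The estradiol arrays parted on Pdk4, at 13.92 and 13.85 in replicates 29 and 30 and 12.98, 12.58 and 12.58 in replicates 33, 34 and 35.

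With estradiol 3 lists fell. The immediate early genes had a median change of −0.17, with 13 of 15 members negative (camera adjusted p = 0.00443; adjusted p = 0.958 with an estimated correlation). Adjusted over the list alone, 4 members passed, namely Klf4, Klf6, Atf3 and Fos, and none passed over all genes. The heat shock list had a median of −0.19, with 13 of 14 members negative (camera adjusted p = 0.00443; adjusted p = 0.958 with an estimated correlation). In that list Hsp90aa1 and Dnaja1, a chaperone and a co-chaperone, passed over the list alone. The glucocorticoid-responsive list had a median of −0.23, with 14 of 15 members negative (camera adjusted p = 0.0471; adjusted p = 0.958 with an estimated correlation). There Cdkn1a, a cell cycle inhibitor, passed over the list alone. In estradiol replicate 33 the mean level of the immediate early list stood at −0.49, against −0.13 to −0.08 in the other estradiol arrays. Placebo replicate 33 stood at 0.57, against −0.16 to 0.14 in the other placebo arrays, so the groups overlapped. Without estradiol replicate 33 the list's median was −0.14 (camera adjusted p = 0.00716), and without estradiol replicates 29, 34 and 35 it was −0.31, −0.27 and −0.28, with the call kept each time. It was kept whichever of the 20 arrays was left out. Without estradiol replicate 33 the heat shock median was −0.12, with the call kept, and the glucocorticoid-responsive median was −0.10, with the call lost (camera adjusted p = 0.217). That call was also lost without any 1 of estradiol replicates 29, 30 and 34, placebo replicates 32 and 36 or beta-titled replicate 32. The heat shock call was lost without placebo replicate 36, and both calls were lost after quantile normalization (camera adjusted p = 0.0718 for heat shock and 0.138 for glucocorticoid-responsive genes). The number of lists was 6 without placebo replicate 34 and 1 without placebo replicate 36. The extracellular matrix and fibroblast list, with 14 members above and 15 below placebo, had a median of −0.00485 and did not pass (camera adjusted p = 0.858). Of the 27 genes called with 16α-LE2, 26 changed in the same direction with estradiol against placebo, 12 of them at an unadjusted limma p under 0.05. Their estradiol change was a median of 0.39 times that of 16α-LE2. Shared placebo arrays favour such a match, and 20 of the 27 also matched in the beta-titled group against placebo. For estradiol against the beta-titled arrays, 23 of the 27 matched. Among estrogen target genes known from other tissues Ptgds, a prostaglandin D synthase, was 1.41-fold above placebo and passed over the list alone (adjusted p = 0.0108) but not over all genes (limma adjusted p = 0.499).

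**Figure D2:**
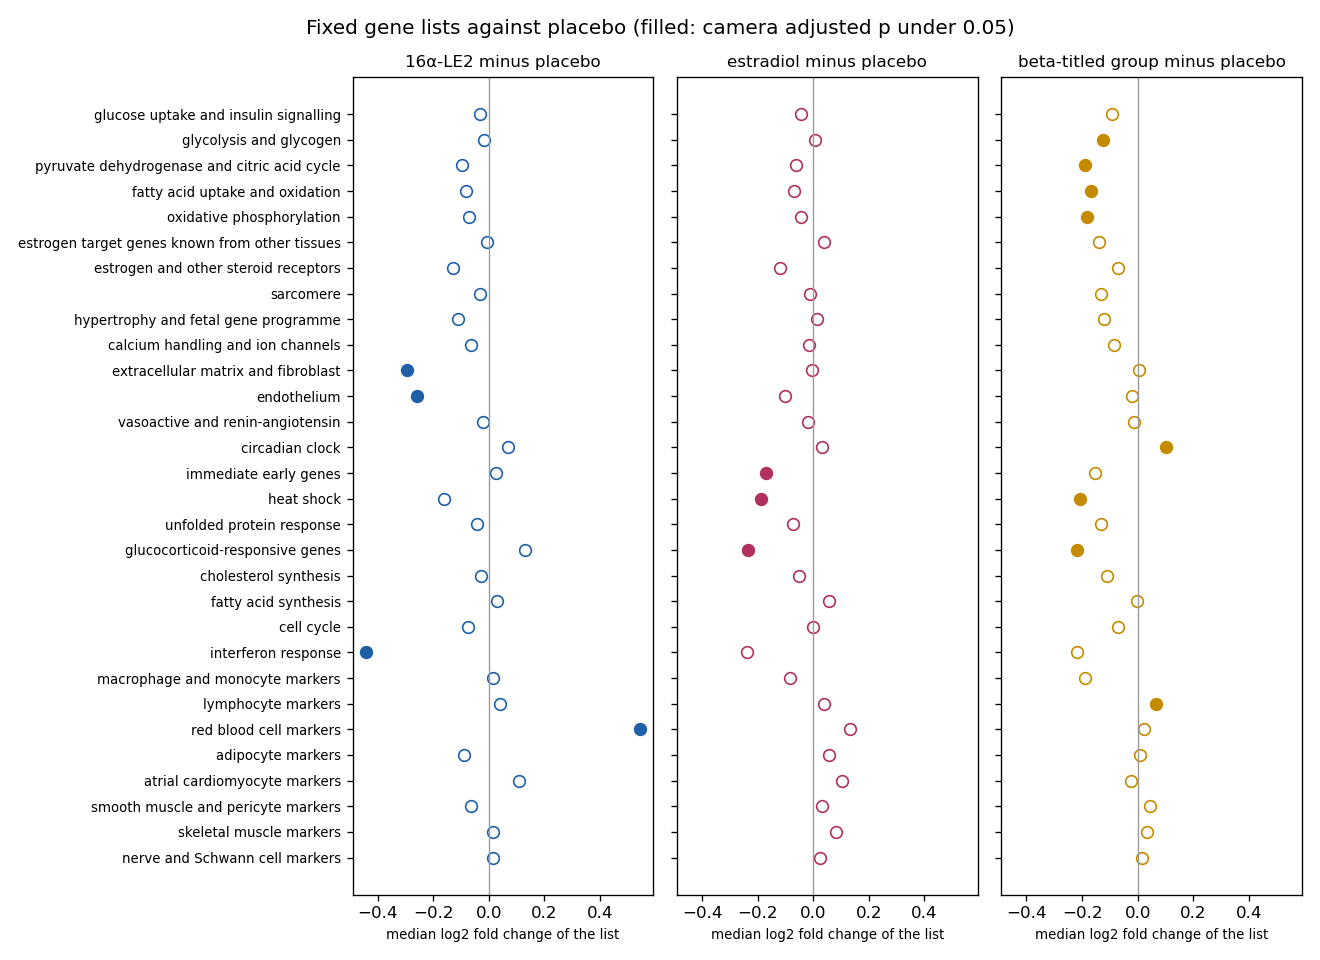
Median log2 fold change (horizontal axes) of the members of each of 30 fixed gene lists against placebo, for 16α-LE2, estradiol and the beta-titled group; filled points mark a camera adjusted p under 0.05 at a preset correlation. The extracellular matrix and fibroblast list lies at −0.30 with 16α-LE2, at −0.00485 with estradiol and at 0.00386 in the beta-titled group.

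The agonists were then set against each other. Relative to estradiol, Nrep was 2.11-fold lower with 16α-LE2 and Col14a1, a fibril-associated collagen, 1.55-fold lower (limma adjusted p = 0.027 for both), and no other gene passed, while 627 had an unadjusted p under 0.05. The next genes by p lay just outside the threshold, with Col3a1 at −1.12 ± 0.20 SE on the log2 scale (limma adjusted p = 0.0502), Sparc at −0.61 ± 0.11 and Myh7 at 1.17 ± 0.22 (limma adjusted p = 0.0507 for both). Of 30 alternative settings, the call was lost in 11 for Col14a1 and 10 for Nrep. The count went from 0 to 11 over leaving out each array in turn. It was 0 without any 1 of 16α-LE2 replicates 30, 32, 33 and 34 or estradiol replicates 30, 34 and 35, 1 without estradiol replicate 29, 11 without 16α-LE2 replicate 29, 8 and 6 without placebo replicates 33 and 36, and 4 without placebo replicate 34 or beta-titled replicate 31 or 35. The extracellular matrix and fibroblast list was lower with 16α-LE2 than with estradiol, by a median of −0.33 with 26 of 29 members negative (camera adjusted p = 4.06e-17; adjusted p = 0.0378 with an estimated correlation). The other 6 lists that passed did not hold with an estimated correlation. They included the immediate early genes, all 15 of which were higher with 16α-LE2 (median 0.27, camera adjusted p = 4.91e-08; adjusted p = 0.195 with an estimated correlation), and the glucose uptake and insulin signalling list (median 0.06, camera adjusted p = 0.0184; adjusted p = 0.759 with an estimated correlation). For Slc2a1 the difference between the agonists was 0.14 log2 units with a 95% interval from −0.06 to 0.35 (limma adjusted p = 0.875), and for Ptgds it was −0.02 with an interval from −0.28 to 0.25 (limma adjusted p = 0.986). These intervals leave room for differences of either sign, so equal action was not shown.

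Across the 12082 genes, which are not independent replicates, the log2 fold changes of 16α-LE2 and estradiol against placebo correlated with Pearson's r = 0.61. Both share the placebo arrays, and 100 simulations of unchanged groups that shared them gave a mean r of 0.50 (0.478 to 0.524). The covariance was 0.0127 against 0.00618 in the simulations, a difference of 0.0065. The simulated values need not hold for the real arrays, on which genes can deviate together. The spread of the real r, estimated by leaving out arrays in turn (jackknife), was 0.163, larger than the gap between 0.61 and 0.50. These simulations therefore cannot decide whether r lay above what shared placebo arrays give. With the placebo arrays split between the comparisons r averaged 0.27 (0.106 to 0.454), and 0.20 without estradiol replicate 33. With no array shared, 16α-LE2 minus placebo against estradiol minus the beta-titled group gave 0.26, and 0.0911 without estradiol replicate 33, and 16α-LE2 minus the beta-titled group against estradiol minus placebo gave 0.0699.

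The beta-titled group against placebo asked whether these samples, called control solution in 1 label, differed from placebo. No gene passed with limma (smallest adjusted p = 0.397), 689 had an unadjusted p under 0.05, and the count was 0 in every alternative setting run. The genes of smallest p, none of which passed, were led by Mpp7, a membrane scaffold protein (log2 change −0.66 ± 0.13 SE, limma adjusted p = 0.397), Cdkn1a (−0.85 ± 0.19) and Tnfrsf12a, a receptor of the tumour necrosis factor family (−0.76 ± 0.17), the last pair with a limma adjusted p of 0.707. Ankrd23, Zfp867, Timm10, Plscr1, Ces1d and Tent5a were also below placebo, and Dnm1 was 1.16-fold above it. Slc2a1 had a log2 change of −0.08 ± 0.10 SE and Myh7 one of 0.45 ± 0.22 SE. The values of Slc2a4 (−0.10 ± 0.10), Nppa (−0.16 ± 0.19) and Pdk4 (−0.41 ± 0.20) did not pass either.

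In this comparison 8 lists passed, 6 lower and 2 higher, and none held with an estimated correlation. The oxidative phosphorylation list had all 33 members below placebo, with a median change of −0.18 (camera adjusted p = 6.43e-12; adjusted p = 0.583 with an estimated correlation). By array the groups overlapped in the mean level of this list, taken from each gene's mean over all arrays. It was −0.21, −0.30, −0.15, 0.03 and 0.08 in beta-titled replicates 31, 32, 33, 35 and 36. In placebo replicates 31, 32, 33, 34 and 36 it was 0.21, 0.17, 0.12, −0.04 and −0.11. The pyruvate dehydrogenase and citric acid cycle list had a median of −0.19 (27 of 28 members negative, camera adjusted p = 1.46e-07; adjusted p = 0.583 with an estimated correlation). The fatty acid uptake and oxidation list had a median of −0.17 (26 of 28, camera adjusted p = 0.00131; adjusted p = 0.583 with an estimated correlation), and the glycolysis and glycogen list one of −0.12 (21 of 23, camera adjusted p = 0.0293; adjusted p = 0.662 with an estimated correlation). The heat shock list stood at −0.21 (camera adjusted p = 0.0026; adjusted p = 0.583 with an estimated correlation) and the glucocorticoid-responsive list at −0.22 (camera adjusted p = 0.044; adjusted p = 0.662 with an estimated correlation). The circadian clock list stood at 0.10 (camera adjusted p = 0.0432) and the 4 tested lymphocyte markers at 0.07 (camera adjusted p = 0.0359), with an adjusted p = 0.583 for both with an estimated correlation. The number of lists was 5 without beta-titled replicate 32 or 33 and 4 without estradiol replicate 33 or placebo replicate 32. The oxidative phosphorylation and citric acid cycle calls stayed whichever array was left out, the fatty acid call was lost without placebo replicate 32 and the heat shock call without placebo replicate 36. The glycolysis call was lost without beta-titled replicate 32 or 33, estradiol replicate 33 or placebo replicate 32, 34 or 36, and the circadian call without beta-titled replicate 31, 32, 33 or 35, estradiol replicate 33 or placebo replicate 31 or 36. The glucocorticoid-responsive call was lost without beta-titled replicate 33, estradiol replicate 33 or placebo replicate 32 or 36, and the lymphocyte call without beta-titled replicate 32 or 36, estradiol replicate 33 or placebo replicate 32. Without beta-titled replicate 32 the medians of the fatty acid, glycolysis and heat shock lists were −0.08, −0.08 and −0.12, and that of the heat shock list was also −0.12 without replicate 31. The glucocorticoid-responsive median was −0.13 without beta-titled replicate 33 and −0.14 without placebo replicate 32, the lymphocyte median 0.04 without placebo replicate 32 and the circadian median 0.06 without placebo replicate 31. After quantile normalization none of these 8 lists passed, and the glycolysis and glycogen list and the fatty acid list turned sign, to medians of 0.02 and 0.00397. The 2 arrays of narrowest spread in the series belong to this group, with SDs of 1.30 for replicate 32 and 1.32 for replicate 31. Across genes, which are not independent replicates, the log2 change against placebo fell with the mean level (Spearman's rho −0.58, against −0.40 for estradiol and −0.36 for 16α-LE2).

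Against 16α-LE2 the beta-titled group differed in 21 genes, 12 higher and 9 lower, with 676 at an unadjusted p under 0.05. Aplnr (3.22-fold), Col3a1 (2.97-fold), Nrep (2.32-fold), Sparc (1.86-fold) and Col8a1 (1.75-fold) were higher in the beta-titled group, with limma adjusted p from 0.00042 for Col3a1 and Sparc to 0.0156 for Aplnr and Col8a1. With the mean of its probe sets the log2 change of Aplnr was 1.07 in place of 1.69, and it did not pass. Nppb, the B-type natriuretic peptide gene, was 1.97-fold lower (limma adjusted p = 0.0156), Mt2, a metallothionein, 1.88-fold lower (limma adjusted p = 0.0244), Spon1 1.67-fold lower (limma adjusted p = 0.00359), Ptgds 1.60-fold lower (limma adjusted p = 0.0225) and Asb11 1.54-fold lower (limma adjusted p = 0.0469). Slc2a1, picked here after its value was seen, was also lower, by −0.47 ± 0.10 SE on the log2 scale (limma adjusted p = 0.0469). Its call was not counted over the alternative settings, unlike those of the genes above. The call for Asb11 was lost in 21 of 30 alternative settings (adjusted p up to 0.237), that for Mt2 in 10, Ptgds in 9, Aplnr in 7, Col8a1 in 6 and Nppb in 5, while Col3a1, Nrep, Sparc and Spon1 passed in all 30. Of the 21 genes, 13 were among the 27 of 16α-LE2 against placebo, all 13 with the opposite sign. Both comparisons use the same 16α-LE2 arrays, and when these were split between them the overlap averaged 1.3 genes (0 to 3), from an average of 5.8 and 7.15 genes called. The extracellular matrix and fibroblast list was higher in the beta-titled group by a median of 0.29, with 24 of 29 members positive (camera adjusted p = 6.36e-24; adjusted p = 0.00843 with an estimated correlation). In all 15 lists passed and 2 held with an estimated correlation, the other being the red blood cell list, which was lower (median −0.53, adjusted p = 0.0496 with an estimated correlation). Leaving out each array in turn gave 7 to 37 genes: 7 without 16α-LE2 replicate 30 or 33 or beta-titled replicate 31, 8, 9 and 10 without beta-titled replicate 32, 16α-LE2 replicate 34 and 16α-LE2 replicate 32, 11 without beta-titled replicate 33, and 37 without estradiol replicate 33.

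The beta-titled group against estradiol had no gene past the threshold with limma (smallest adjusted p = 0.213; 463 with an unadjusted p under 0.05), and 1 gene passed without beta-titled replicate 35. Of 30 lists 4 passed and none held with an estimated correlation. The genes of smallest p were Ptgds (log2 change −0.69 ± 0.13 SE, all 5 beta-titled samples below all 5 estradiol samples, limma adjusted p = 0.213), Ano10 (−0.82 ± 0.17) and Mmp3, a matrix protease (−0.71 ± 0.15), the last pair with a limma adjusted p of 0.36, and Tmem100 (0.59 ± 0.14) and Meig1 (0.52 ± 0.13).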

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

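The tests of RNA degradation, of other groupings of the samples for the counts of genes, and of what those groupings share were chosen after the results they concern had been seen. How the fibroblast markers, the quantile-normalized matrix list and the lists matched on level were read was also settled after their values were seen. A single array stood far from the other 4 of its group in 10 of 154 groups of 5 values examined, where chance would give about 1 in 20 groups. Of the 10, 4 were estradiol replicate 33: its median correlation with other arrays was 0.932 (0.987 to 0.988 in the other estradiol arrays), its median value was 7.03 (6.91 to 6.94), its level of the immediate early list was −0.49, and Meig1 stood at 6.47 (7.11 to 7.29). Estradiol replicate 30 was high for Sfpq at 8.71 and for Tmem100 at 9.18. Beta-titled replicate 35 was high for Myh7 at 10.64 (9.93 to 10.01), and beta-titled replicate 31 low for Tent5a at 8.43. Placebo replicate 36 was high for the interferon response list at 1.37 (−0.29 to 0.18), and placebo replicate 34 for the red blood cell list at 0.12 (−0.25 to −0.20).

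Estradiol replicate 33 differed from the mean of the other 4 estradiol arrays with an SD of 0.402 log2 units, against 0.170 to 0.218 for those arrays. RNA degradation was argued against, because 11 of the 19 other arrays had a larger 3' minus 5' difference for Gapdh and 13 had one for β-actin. The mean of its poly-A control probe sets was 7.31, below that of every other array (7.69 to 9.15). The mean of its hybridization controls was 10.43, with only estradiol replicate 34 lower at 10.29. What lies behind these control values was not tested. An excess of cells of another type did not show in the tested markers. No marker list lay above the other estradiol arrays by more than a median of 0.329 log2 units (adipocyte markers). The expression filter used the mean over all arrays, so it could drop markers present in this array alone. It left 5 of 10 adipocyte, 4 of 12 lymphocyte and 6 of 12 skeletal muscle markers on the array. Such an excess was therefore not excluded. A smaller share of a cell type was not tested. The atrial and endothelium lists lay below those arrays, with medians of −0.602 and −0.369. Weak signal of dim probe sets stays open: the deviations were 1.41 times as wide in the dimmest genes as in the brightest, between the bounds set beforehand. Apart from an excess of cells of another type, no biological explanation was tested.

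Matrix genes were lower with 16α-LE2, with a list median of −0.30. The value range of the arrays was argued against as the whole cause, since after quantile normalization the median was −0.20 (−0.24 to −0.14 leaving out each sample) and the list still passed (camera adjusted p = 1.18e-14). That is less than 0.75 of the first value, the bound set beforehand, so the range may carry part of the size. A smaller share of fibroblasts stays open, because 12 markers of fibroblast identity, 4 of them also in the matrix list, had a median of −0.23 (−0.31 to −0.19), although Tcf21 had −0.00154 and Dpep1 had 0.31. An effect of receptor α on matrix genes also stays open and was not tested apart from the treatment itself.

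Oxidative phosphorylation genes were lower in the beta-titled group, with a list median of −0.18. A narrow value range of 2 arrays is a candidate explanation: after quantile normalization the median was −0.0141, and without beta-titled replicates 31 and 32 it was −0.0846. The high level of the list stays open as well: 1.25% of 10000 random lists matched on mean level had a median as low, but this share was 0.05% to 4.42% leaving out each sample, and the median of those lists was already −0.14. Whatever the beta label stands for remains open and untested.

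Other groupings of the 10 samples of a comparison, 100 in each case with the real one included, were run for each count. For 16α-LE2 against placebo 1 of 100 groupings, the real one, gave as many genes as 27, and the highest other gave 1. No other grouping drawn came near this count. However, 1 of 100 is the smallest share that 100 groupings can give, and the shares were not adjusted for the several counts tested. A structure of the samples other than the treatment is not excluded by such a share. The matrix list shift of 16α-LE2 against placebo, 0.296 in size, was reached by 1 grouping, the real one, with 0.288 as the highest other. For the beta-titled group against 16α-LE2 the real grouping alone (1 of 100) gave 21 genes, with 1 as the highest other, and the same limits hold. For 16α-LE2 against estradiol 2 of 100 gave as many as 2 genes, with 8 as the highest other. That share is small, but it was 1 of several counts tested this way without adjustment. Another grouping called more genes than the real one, and the count was 0 without any 1 of 7 arrays. Chance was therefore not excluded for this count, and the 2 genes carry little weight. With 0 genes called, all 100 groupings reached the real count for estradiol against placebo (highest other 897), for the beta-titled group against placebo (highest other 58) and for the beta-titled group against estradiol (highest other 1208). Groupings that call so many genes point to a structure among the samples other than the groups. All 4 groupings that called over 50 genes for estradiol against placebo set estradiol replicates 29 and 30 against 34 and 35, as 18 of the 100 groupings did, and no grouping without this division called more than 1 gene. For the beta-titled group against estradiol 2 of the 3 groupings over 50 did so, and the highest without it called 181. What divides these arrays was not tested, and the groupings of the beta-titled group against placebo, which hold no estradiol array, were not examined for it. Chance was not excluded for the counts of lists: 90 groupings gave as many as the 4 lists of 16α-LE2 (highest other 14), 83 as many as the 3 of estradiol (highest other 10) and 41 as many as the 8 of the beta-titled group (highest other 14). The oxidative phosphorylation shift of 0.182 in size was reached by 11 groupings, with 0.301 as the highest other, so chance was not excluded there either.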

How the results depend on the processing

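A left-out array outside a comparison acts on its count of genes only through the spread shared by all groups. Otherwise the cause of the changes below was not tested. Leaving out the 3 arrays of narrowest spread and setting estradiol or 16α-LE2 against the beta-titled samples were chosen after results had been seen. The number of genes with 16α-LE2 against placebo was 16 with the mean of a gene's probe sets, 357 with array weights, 62 at an adjusted p under 0.1, 71 with placebo and beta-titled samples pooled (26 of the 27 kept), and 60 without the 3 arrays of narrowest spread. After quantile normalization it was 23 (18 of the 27 kept). For 16α-LE2 against estradiol it was 4 without a filter, 20 with array weights, 6 at an adjusted p under 0.1, 1 without the 3 arrays of narrowest spread, and 0 with the mean of a gene's probe sets or with every probe set on its own. For the beta-titled group against 16α-LE2 it was 32 after quantile normalization, 13 with the median of each array set equal, 46 with only the 2 groups compared in the fit, 122 with array weights, 34 at an adjusted p under 0.1 and 10 without the 3 arrays of narrowest spread. Lists with 16α-LE2 numbered 7 without a filter or with a filter at the 25th percentile, and 2 with an estimated correlation. Lists with estradiol numbered 1 after quantile normalization, 6 with array weights, and 0 with an estimated correlation or with fry. Lists in the beta-titled group numbered 2 after quantile normalization, neither of them among the 8, 0 with an estimated correlation, 1 with fry and 3 without the 3 arrays of narrowest spread. The correlation of fold changes was 0.271 with placebo samples split and 0.258 with estradiol set against the beta-titled samples (0.0911 without estradiol replicate 33), and 0.0699 with the controls exchanged. Leaving out each of the 20 arrays gave 8 to 74 genes for 16α-LE2 against placebo, 0 to 1 for estradiol against placebo, 0 to 0 for the beta-titled group against placebo, 0 to 11 for 16α-LE2 against estradiol, 0 to 1 for the beta-titled group against estradiol and 7 to 37 for the beta-titled group against 16α-LE2. It gave 3 to 7 lists with 16α-LE2, 1 to 6 with estradiol and 4 to 12 in the beta-titled group, and correlations of 0.508 to 0.674. With the replicate number as a block, 36 genes passed for 16α-LE2 against placebo (15 of the 27 kept), 4 for 16α-LE2 against estradiol and 15 for the beta-titled group against 16α-LE2, and 6 lists passed with estradiol. The counts of 0 genes stayed at 0. Samples that share a number did not deviate together: 6 of 17 pairs had a correlation over 0.1 (−0.346 to 0.509), and 3 of 20 samples correlated best with their own number. This check cannot see a drift along the numbers, which was not tested. Between the lowest and highest number the heat shock level went from −0.23 to 0.06 with 16α-LE2 and −0.30 to 0.44 in the beta-titled group. It went from 0.003 to 0.54 with placebo, but from −0.09 to −0.17 with estradiol. Numbers 29 and 30 occur only with 16α-LE2 and estradiol, and 36 only with placebo and the beta-titled group. Only genes that did not pass turned sign. Slc2a4 turned with estradiol, to −0.00438 with the mean of its probe sets, −0.0282 with the median of each array set equal, −0.0298 with the block, and between −0.0796 and 0.0616 when each array was left out. It turned with 16α-LE2, to 0.0845 after quantile normalization, 0.0185 with pooled controls and 0.0157 without placebo replicate 34 (−0.0534 to 0.0157 leaving out each array), and in the beta-titled group, to 0.0738 after quantile normalization. Nppa turned in the beta-titled group, to 0.0297 after quantile normalization and 0.0115 without beta-titled replicate 32 (−0.296 to 0.0115 leaving out each array), and with estradiol, to −0.0631 with the block. Myh7 turned with estradiol, to −0.0150 with the block and −0.0453 with pooled controls. The alternative pseudocount does not apply to values that are already logarithms and was not run.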

Other observations

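The values in this part were picked after the results had been seen. The hypertrophy and fetal gene programme list did not pass with 16α-LE2 (camera adjusted p = 0.496), with 5 members above and 10 below placebo, a median change of −0.11, a mean of 0.06 and a test that pointed up. Besides Myh7, which passed over all genes, 2 of its 15 members passed over the list alone, in opposite directions: Nppb had a log2 change of 0.51 (limma adjusted p = 0.298; 0.0367 over the list alone), and Igf1, a growth factor gene, had one of −0.49 (limma adjusted p = 0.15; 0.00962 over the list alone). The levels of the oxidative phosphorylation list differed between the beta-titled arrays, at −0.28, −0.37, −0.22, −0.04 and 0.01 from the placebo mean in replicates 31, 32, 33, 35 and 36. In estradiol replicate 33, 186 genes lay more than 1 log2 unit from the mean of the other estradiol arrays, and its atrial marker list lay 0.60 below theirs (median −0.602). The level of the circadian clock list also parted the estradiol arrays, at −0.39, −0.11 and −0.21 in replicates 29, 30 and 33 and 0.36 and 0.25 in replicates 34 and 35. It was −0.07 to 0.02 in the 16α-LE2 arrays, −0.03 to 0.08 in the beta-titled arrays and −0.14 to 0.10 in the placebo arrays. The placebo range takes in estradiol replicate 30. The list did not pass with estradiol against placebo (camera adjusted p = 0.754).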
